A study of Homo sapiens with 24 samples.

How the data were processed

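Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on tumours of a patient-derived luminal breast cancer xenograft, that is, human breast tumour tissue grown in immunodeficient mice. The mice received estrogen (E2) or estrogen plus progesterone (E2+P4) from the time of transplantation, per the labels' protocols. The labels give 24 libraries in 8 groups, with 3 replicates of an estrogen receptor (ER) ChIP, a progesterone receptor (PR) ChIP, an IgG control ChIP and an input for each treatment. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate mice.

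The authors deposited 1 file of peaks with no header, holding 15400 peaks in 4 lists. The peak names give the treatment, the antibody and the word IgG, and no replicate number, so each list was taken as 1 list per treatment and antibody without separate replicates. How the 3 replicates were combined is not given in the sources used here. The word IgG in the names was read as the control used for calling, and no list of IgG or input peaks was analysed here. The submitters' processing notes name cutadapt, Bowtie2, Bowtie, HOMER and the builds GRCh37 and hg19, without versions or roles. Each list has 1 fixed peak width, which is 412 bp for E2 ER, 444 bp for E2+P4 ER, 146 bp for E2 PR and 230 bp for E2+P4 PR.

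Each peak carries a whole-number score that the authors deposited without a statement of its unit. Scores ran from 89 to 7081, and 885 peaks held exactly 1000. All 486 E2 ER peaks with that score had an E2+P4 ER peak at the same place, against 87.7% of the 138 other E2 ER peaks scored between 950 and 1050. In the E2+P4 ER list the gap was smaller, with all 395 such peaks against 97.1% of the 136 others. The value 1000 was not trusted as a rank, and the score was used only within a list. It served to split a list at its median, to divide it into 8 bins, to name its 5 highest peaks, to compare shared with treatment-specific peaks, and to shorten the longer of a pair of lists to the length of the shorter. The median splits place the peaks scored 1000 in the upper part. Score medians of shared and treatment-specific peaks were also compared without the peaks scored 1000. Peak lists hold no read counts, so sequencing depth is unknown, and a site missing from a list is a site not called, not a site shown to be unbound.

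Coordinates are given in hg19, counted from 1. A peak was called shared when it overlapped a peak of the other list by at least 1 bp, computed with an interval function that gave the same counts as bedtools 2.31.1 for every ordered pair of lists. Chance overlap was measured by placing the peaks of a list at random 1000 times on the same chromosomes, between the first and the last peak of any list. This is a permutation of positions, and the smallest p it can give is 0.001. The alternatives and the counts in windows used 200 placements, with a smallest p of 0.005. Random placement ignores open chromatin and mappability, so it understates the overlap of unrelated chromatin factors. Shares carry 95% Wilson intervals, which cover counting error over peaks only. Peaks are not replicates, and every p-value compares the deposited lists, not animals.

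Differences of shares were tested with two-sided Fisher's exact tests, and medians of scores with two-sided permutation tests of 100000 resamples, whose smallest p is 1e-05. Tests over the 23 chromosomes were adjusted by Benjamini-Hochberg with a threshold of 0.05. Clustering was the share of peaks with another peak of the same list within 12.5 kb, midpoint to midpoint. Peaks were also counted in fixed 1 Mb windows. These windows, the tests over chromosomes, and the comparisons of PR classes, of clustered with dispersed PR peaks, of ER-bound shares by class and of the ER lists of either treatment were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. On simulated lists with a known shared share, the overlap function recovered 60.1% for 60.0% in 7374 E2 ER peaks, 30.0% for 30.0% in 756 E2 PR peaks against E2+P4 PR, and 10.1% for 10.0% in 756 E2 PR peaks against E2 ER. The shared peaks were planted so close to their partners' midpoints that each had to overlap. The simulation therefore checks the counting only, not looser overlaps.

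The rule for named items was fixed before the data were examined. It took a few fixed genes, members of fixed gene lists nearest to peaks, and the 5 highest-scoring peaks per list, with positions alone to be named where no annotation of the build was at hand. An hg19 annotation and genome were not used here. The available gene table is of GRCh38.p14, and coordinates were not converted between builds. The planned tests of promoter share, motif content, gene lists near peaks and peaks at tRNA genes were therefore not made, and peaks are named by position. The gene table served only in the closing part, for the chromosome a gene lies on and for which genes are neighbours. No test of differential binding across replicates was made, since the lists hold no counts per library.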

Results

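The series asked where ER and PR, the nuclear receptors for estrogen and progesterone, bind chromatin in a luminal breast cancer xenograft, and how their binding sites differ when progesterone is added to estrogen. The peak lists held 7374 ER peaks under E2, 6889 ER peaks under E2+P4, 756 PR peaks under E2 and 381 PR peaks under E2+P4. The ER list was 9.75 times as long as the PR list under E2 and 18.1 times as long under E2+P4. Each list stands for the 3 libraries of its group without separate values per library, so the numbers of peaks carry no replicate error and were not tested between treatments. The lists also stop at different scores, with a lowest score of 94 for E2 ER, 89 for E2+P4 ER, 239 for E2 PR and 191 for E2+P4 PR. Together the lists marked 10082 distinct sites, of which 4838 had an ER peak under both treatments and no PR peak. Chromosomes 1 to 22 and X carried 7361 of the E2 ER peaks and 6871 of the E2+P4 ER peaks. The remaining 13 and 18 ER peaks lay on unplaced or unlocalised contigs of hg19. On those contigs there were 0 of 756 E2 PR peaks, which allows a share of up to 0.397%, and 0 of 381 E2+P4 PR peaks, which allows up to 0.787%.

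The first comparison asked whether ER occupied other sites once progesterone was added. Most ER sites were found under both treatments. An overlapping E2+P4 peak was present at 4902 of 7374 E2 ER peaks (66.5%, 95% interval 65.4 to 67.6%), and these made up 71.2% of the E2+P4 list (70.1 to 72.2%). Random placement gave 22.2 shared peaks on average and at most 35 in 1000 placements (permutation p = 0.001, the smallest possible). The midpoints of shared ER peaks lay a median of 17.0 bp apart. Sites found in only 1 of the lists numbered 2472 for E2 and 1987 for E2+P4.

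Treatment-specific ER sites were mostly low-scoring. The median score was 906.5 for shared E2 ER peaks and 194 for E2-specific ones, and 749 against 175 in the E2+P4 list (permutation p = 1e-05 for each list, the smallest possible). Among E2 ER peaks the shared share rose from 15.4% in the lowest of 8 score bins to 99.9% in the highest, where 920 of 921 peaks were shared. The E2+P4 ER list gave 19.3% in the lowest bin and 99.9% in the highest. At or above the list median, 231 E2 ER peaks (6.27%) and 161 E2+P4 ER peaks (4.66%) were specific to their treatment. The 5 highest-scoring E2 ER peaks all had an E2+P4 counterpart. They lay at chromosome 16, 48439411 to 48439822 (score 7071), chromosome 19, 18392467 to 18392878 (7063), chromosome 10, 32047898 to 32048309 (7057), chromosome 18, 46500960 to 46501371 (7023) and chromosome 13, 28074789 to 28075200 (7014). The 5 highest E2+P4 ER peaks were likewise shared with E2. Their positions were chromosome 2, 116249076 to 116249519 (7081), chromosome 4, 95393566 to 95394009 (7079), chromosome X, 5320522 to 5320965 (7020), chromosome 4, 991564 to 992007 (6992) and chromosome 1, 235804856 to 235805299 (6980). Peaks scored exactly 1000 may outrank these.

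**Figure D1:**
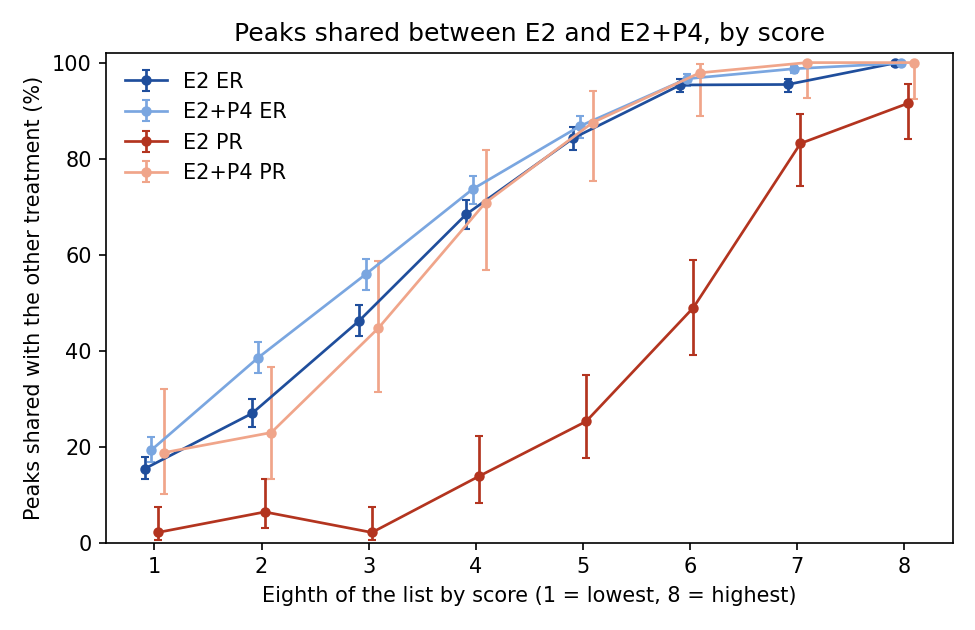
Share of peaks (%, y axis) that overlap a peak of the same antibody under the other treatment, in 8 score bins of equal size per list (x axis); points are shares and bars 95% Wilson intervals. The E2 ER share runs from 15.4% to 99.9% and the E2 PR share from 2.11% to 91.5%.

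E2-specific and E2+P4-specific ER peaks were spread differently over the chromosomes. Of 23 chromosomes, 6 differed after Benjamini-Hochberg adjustment of Fisher's exact tests. By these exact tests, chromosome 1 held 11.9% of the E2-specific and 9.21% of the E2+P4-specific peaks (adjusted p = 0.0343), chromosome 7 held 4.49% against 2.87% (adjusted p = 0.0343) and chromosome 19 held 4.81% against 3.17% (adjusted p = 0.0343). The E2+P4-specific share was higher on chromosome 15, at 3.17% against 1.62% (exact test, adjusted p = 0.0195), on chromosome 6, at 4.18% against 2.71% (adjusted p = 0.0343), and on chromosome 3, at 8.20% against 6.23% (adjusted p = 0.0447). Neighbouring peaks are not independent, which makes these p-values too small.

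The second comparison asked where PR was found without and with added progesterone. The E2 list was 1.98 times as long as the E2+P4 list. PR peaks present under both treatments numbered 258, which is 34.1% of the E2 list (30.8 to 37.6%) and 67.7% of the E2+P4 list (62.9 to 72.2%). Random placement shared at most 2 peaks (permutation p = 0.001). Shared PR peaks had a median score of 1496 in the E2 list against 401 for the 498 E2-specific peaks, and 884.5 in the E2+P4 list against 267 for the 123 E2+P4-specific peaks (permutation p = 1e-05 for each list). At or above the list median, 96.4% of E2+P4 PR peaks had an E2 counterpart (92.7 to 98.2%), and 61.5% of E2 PR peaks had an E2+P4 counterpart (56.6 to 66.3%). The E2 list was also shortened by score to the length of the E2+P4 list, a choice made after the data were seen. Of its remaining peaks, 61.7% were shared. The cut removed the lowest-scoring peaks, so the 34.1% depends on length and score together.

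The highest-scoring PR sites of each list had a PR peak in the other list. The E2 list was headed by 2 neighbouring peaks on chromosome 1, at 145399232 to 145399377 (score 7017) and 145397864 to 145398009 (6724). These were followed by chromosome 17, 47269820 to 47269965 (5764), chromosome 16, 14379655 to 14379800 (5715) and chromosome 16, 22207057 to 22207202 (5409). All 5 had an E2+P4 PR peak and none an ER peak. The E2+P4 list was headed by chromosome 1, 161493613 to 161493842 (5400), chromosome 1, 145399202 to 145399431 (5300), chromosome 8, 124169434 to 124169663 (4831), chromosome 17, 37310725 to 37310954 (4199) and chromosome 19, 33667854 to 33668083 (3901). Each of these had an E2 PR peak, and only the site on chromosome 19 had an ER peak, in the E2 list.

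The third comparison asked how far ER and PR shared sites. Few PR peaks lay on ER peaks. Under E2, 115 of 756 PR peaks overlapped an ER peak (15.2%, 12.8 to 18.0%), and under E2+P4 29 of 381 did (7.61%, 5.35 to 10.7%). Random placement gave on average 0.167% and 0.189% (permutation p = 0.001 for each). The PR-bound share of ER peaks was 1.56% under E2 and 0.421% under E2+P4. The odds of ER overlap were 2.18 times as high for E2 PR peaks as for E2+P4 PR peaks (Fisher's exact p = 0.000213). The 258 sites shared by the PR lists count in both shares of this test. Without them, an alternative added after the data were seen, 20.5% of the 498 E2 PR peaks and 16 of the 123 E2+P4 PR peaks lay on ER (odds ratio 1.72, Fisher's exact p = 0.0717). Among PR peaks at or above the median score, against ER peaks at or above theirs, the shares were 3.40% and 2.60% (odds ratio 1.32, Fisher's exact p = 0.801). With the E2 PR list shortened to the length of the E2+P4 list, again a choice made after the data were seen, they were 9.19% and 7.61% (odds ratio 1.23, Fisher's exact p = 0.514).

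PR sites that coincided with ER differed from the other PR sites. Of the 498 PR peaks found only under E2, 20.5% lay on an E2 ER peak, against 5.04% of the 258 found under both treatments (odds ratio 4.85, Fisher's exact adjusted p = 4.54e-09). Of the 123 found only under E2+P4, 16 lay on an E2+P4 ER peak (95% interval of the share 8.17 to 20.1%), against 13 of the 258 shared peaks (odds ratio 2.82, Fisher's exact adjusted p = 0.0117). These classes also differed in score and in clustering, with 9.24% of E2-only and 52.7% of shared E2 PR peaks clustered. Clustered PR peaks seldom lay on ER, so the ER shares of the classes cannot be separated from clustering or score. Neighbouring peaks are not independent, which makes these exact-test p-values too small. E2 PR peaks overlapped the ER list of their own treatment more often than the E2+P4 ER list, with 65 peaks on E2 ER alone and 17 on E2+P4 ER alone (exact McNemar p = 8.95e-08). For E2+P4 PR peaks the corresponding numbers were 12 and 13 (exact McNemar p = 1.0). The difference between the treatments in this preference was not tested. With each list restricted to peaks at or above its median score, a choice made after the data were seen, 13 of 382 E2 PR peaks lay on E2 ER and 12 on E2+P4 ER (2 and 1 on that list alone, too few for a test). ER peaks specific to E2 carried an E2 PR peak in 63 of 2472 cases (2.55%), and ER peaks shared by both treatments in 52 of 4902 (1.06%, odds ratio 2.44, Fisher's exact adjusted p = 6.43e-06). The same shares under E2+P4 were 0.554% and 0.367% (exact test, adjusted p = 0.305). Only 10 sites had a peak in all 4 lists. They included chromosome 2, 11679582 to 11680025, chromosome 17, 73030459 to 73030909, and chromosome 14, 21101065 to 21101554, which were chosen as examples after the data were seen.

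PR and ER peaks lay in groups along the genome more often than by chance. Another PR peak within the clustering distance was present for 182 of 756 E2 PR peaks (24.1%, chance 0.961%) and for 135 of 381 E2+P4 PR peaks (35.4%, chance 0.605%). For ER the shares were 17.8% under E2 (chance 7.42%) and 15.1% under E2+P4 (chance 6.77%). These 4 shares exceeded each of 1000 random placements (permutation p = 0.001). Merging peaks within 500 bp left 728 of 756 E2 PR and 363 of 381 E2+P4 PR peaks. It left 7371 of 7374 E2 ER peaks and all 6889 E2+P4 ER peaks. Whether such close PR peaks are 1 site called more than once was not tested, and clustering was not recomputed on merged peaks. Among peaks at or above the median score of their list, the PR shares were 40.8% under E2 and 49.5% under E2+P4, and the ER shares 9.11% and 8.53%, each above all of 200 placements (permutation p = 0.005). Clustered PR peaks were mostly kept between the lists and seldom lay on ER. Under E2, 74.7% of the clustered and 21.3% of the dispersed PR peaks had an E2+P4 PR peak (Fisher's exact adjusted p = 3.39e-38). An E2 ER peak was present at 3.30% of the clustered and 19.0% of the dispersed ones (odds ratio 0.145, Fisher's exact adjusted p = 1.65e-08). Under E2+P4 the ER shares were 2.96% and 10.2% (odds ratio 0.270, Fisher's exact adjusted p = 0.0140). Clustered peaks are neighbours by definition and not independent, which makes these exact-test p-values too small.

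**Figure D2:**
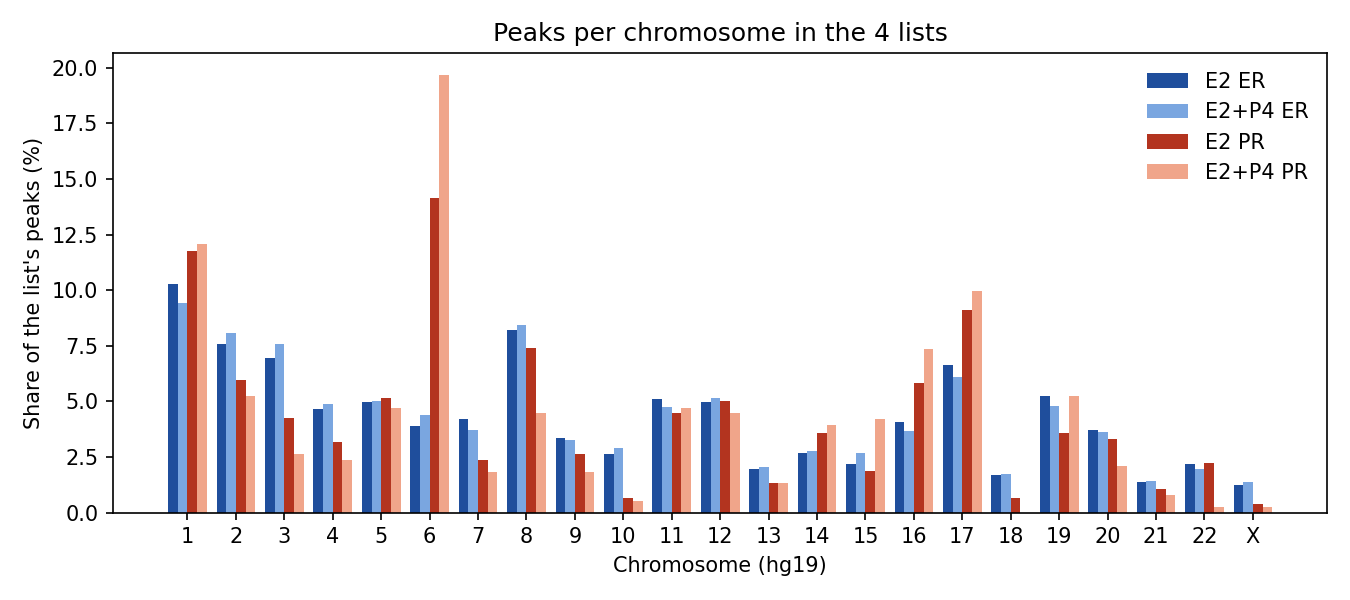
Share of each list's peaks (%, y axis, bars from 0) on chromosomes 1 to 22 and X (x axis) for the 4 lists. Chromosome 6 holds 14.2% of E2 PR peaks and 19.7% of E2+P4 PR peaks, against 3.89% and 4.40% of the ER lists.

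Chromosome 6 stood out. It held 107 of the E2 PR peaks (14.2%) and 287 of the E2 ER peaks (3.89%, odds ratio 4.07, Fisher's exact adjusted p = 9.90e-25). Under E2+P4 it held 19.7% of PR and 4.40% of ER peaks (odds ratio 5.33, Fisher's exact adjusted p = 6.75e-24). Under E2, chromosomes 3 and 10 also differed, each with a lower share of PR than of ER peaks. Under E2+P4, PR shares were higher on chromosomes 6, 16 and 17 and lower on chromosomes 3, 8, 10, 18 and 22. Between the PR lists, 0 of 23 chromosomes differed after adjustment by Fisher's exact test (smallest adjusted p = 0.224), and 3 had an unadjusted p under 0.05. The 258 sites shared by the PR lists count on both sides of this test, which pulls it towards no difference. It therefore does not show that the PR lists are spread alike. Neighbouring PR peaks are not independent, which makes the p-values between PR and ER lists too small.

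Most PR peaks of chromosome 6 fell in the 3 adjoining windows from 26 to 29 Mb. This stretch held 76 E2 PR peaks (10.1% of the list, 8.11 to 12.4%) and 63 E2+P4 PR peaks (16.5%, 13.1 to 20.6%). It held 12 E2 ER peaks (0.163%) and 15 E2+P4 ER peaks (0.218%). Of its E2 PR peaks, 56 had an E2+P4 counterpart, 2 lay on an E2 ER peak and 0 on an E2+P4 ER peak. The next fullest E2 PR windows were chromosome 17 from 8 to 9 Mb with 18 peaks, chromosome 16 from 3 to 4 Mb with 11, chromosome 5 from 180 to 181 Mb with 11, chromosome 14 from 21 to 22 Mb with 10 and chromosome 1 from 161 to 162 Mb with 8. In the E2+P4 list the same windows held 15, 9, 7, 8 and 7 peaks. Together the 10 fullest windows held 19.6% of E2 PR peaks (chance 4.25%) and 31.2% of E2+P4 PR peaks (chance 6.40%). Among peaks at or above the median score of their list, the shares were 35.1% and 47.4%.

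**Figure D3:**
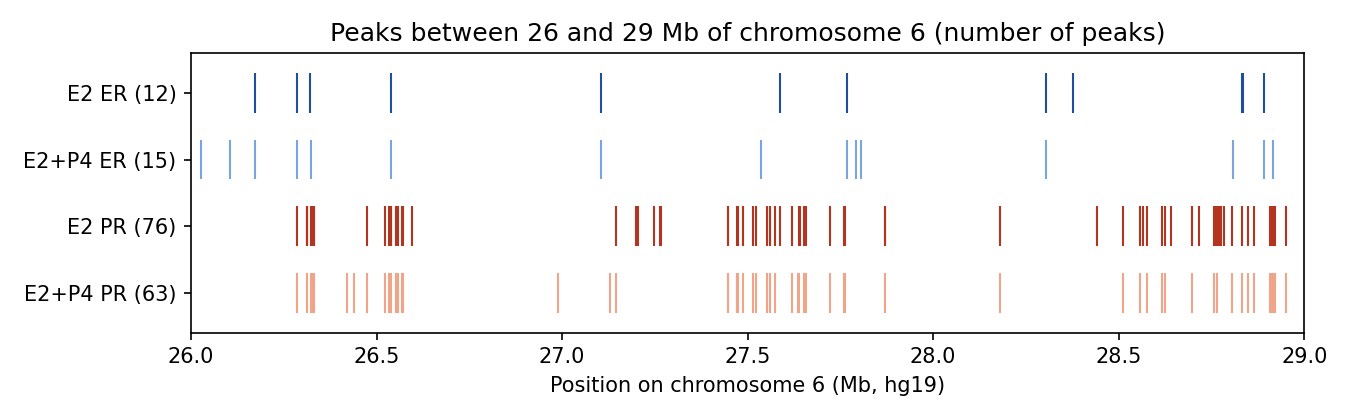
Peak positions (vertical lines at peak midpoints) between 26 and 29 Mb of chromosome 6 in hg19 (x axis, Mb) for the 4 lists (rows, with their number of peaks). The PR rows hold 76 and 63 peaks in matching groups, the ER rows 12 and 15.

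ER peaks were spread more evenly, with 2.64% of E2 ER peaks (chance 1.57%) and 2.54% of E2+P4 ER peaks (chance 1.52%) in their 10 fullest windows. The fullest ER window under both treatments was chromosome 17 from 73 to 74 Mb, with 24 peaks under E2 and 23 under E2+P4. Chromosome 19 from 49 to 50 Mb followed with 23 and 22. Some windows had fewer ER peaks in the E2+P4 list, such as chromosome 16 from 2 to 3 Mb with 18 and 9, and chromosome 11 from 67 to 68 Mb with 17 and 8. Others had more, such as chromosome 8 from 98 to 99 Mb with 14 and 18, and chromosome 17 from 62 to 63 Mb with 15 and 18. These windows were chosen after their counts were seen and were not tested one by one.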

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

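The tests of explanations in this part were chosen after the results were seen, while the odds ratio between the treatments was fixed before.

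ER overlap of PR peaks differed between the treatments, with an odds ratio of 2.18 for E2 against E2+P4. With the longer E2 list shortened by score to the length of the E2+P4 list, its overlap share went from 15.2% to 9.19%. A difference was then no longer detected (Fisher's exact p = 0.514, odds ratio 1.23). Weak peaks of the longer E2 PR list, at which PR and ER coincide more often, could therefore account for the pattern. Without the PR sites shared by both treatments no difference was detected either (odds ratio 1.72, Fisher's exact p = 0.0717). That removes mostly high-scoring peaks, so it gives no support to the account by weak peaks. An IgG control shared by the ER and PR lists of a treatment may add common calls, and E2 PR peaks lay more often on their own ER list, with no such preference detected for E2+P4 PR peaks (exact McNemar p = 1.0) and too few E2 PR peaks at or above the median scores to test it there. That control remains open for E2, since the IgG libraries of the treatments differ and were not analysed here, as does a binding difference between treatments.

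Treatment-specific ER peaks made up 33.5% of the E2 and 28.8% of the E2+P4 list. Calls near the threshold of each list could account for most of them, as only 6.27% of E2 ER peaks at or above the median score were specific. Deeper or better enriched E2 libraries may have lengthened that list, but 4.66% of the E2+P4 peaks at or above the median were specific as well, which does not separate depth from binding. A loss or gain of ER binding with progesterone remains open for all treatment-specific peaks, since a low score alone does not show a threshold call. This includes the 231 and 161 specific peaks in the upper part of the lists. Binding changes cannot be told apart from library differences without values per replicate.

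Many PR peaks clustered in a few windows, and clustered PR peaks seldom overlapped an ER peak, although those windows held ER peaks too. Chromatin that any antibody pulls down could put ER peaks at the same places, and the odds of ER overlap were 0.145 times those of dispersed PR peaks. That cannot exclude such chromatin, since calling against IgG may weaken it in both lists. No IgG or input peaks were analysed to decide it. Chromosome 6 held 33.5% of clustered E2 PR peaks (27.1 to 40.7%) and 5.25% of protein-coding genes in the GRCh38.p14 gene table. Gene-dense chromosomes alone do not account for that excess. Clustered PR peaks still rose in rank with protein-coding genes, with a Spearman rho of 0.519 under E2 and 0.569 under E2+P4. Neither count was divided by chromosome length. Replication-dependent histone genes, also numerous on chromosome 6, are not the whole cause. They are absent in that table from 18 chromosomes that held 50.5% of the clustered E2 PR peaks (43.4 to 57.7%). Both criteria by share replaced a criterion on rho that decided nothing, and the counts per chromosome had been seen by then. Transfer RNA genes remain a candidate explanation: over 23 chromosomes, clustered PR peaks followed the number of tRNA genes that neighbour a tRNA gene with a Spearman rho of 0.820 under E2 and 0.886 under E2+P4, and a cross-reacting PR antibody at those sites stays untested.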

How the results depend on the processing

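The alternatives with lists of equal length, resized peaks, omitted chromosome 6, omitted clustered or shared PR peaks, omitted scores of 1000, and those for windows, chromosomes and the scores of clustered peaks were added after the data were seen. Of 85 alternative values for 27 results, 80 kept their direction and side of the threshold (for numbers of peaks or chromosomes, stayed within 1.5 times). The higher ER overlap of E2 PR peaks lost its call at or above the median scores (odds ratio 1.32, Fisher's exact p = 0.801), with the longer PR list shortened (odds ratio 1.23, p = 0.514) and without PR peaks shared between the treatments (odds ratio 1.72, p = 0.0717). It held under the other 5 alternatives, with odds ratios from 1.86 to 2.39. At or above the median scores, 6 chromosomes in place of 3 differed between PR and ER under E2, and 5 in place of 8 under E2+P4; the cause was not tested. Shares that stayed above chance still moved in size, and chance moved with the setting. The shared share of the E2 PR list ran from 29.7% without chromosome 6 to 61.7% in lists of equal length. The ER overlap of PR peaks was lowest with both the PR and the ER lists cut at their median scores, at 3.40% under E2 and 2.60% under E2+P4. With only the E2 PR list shortened by score, it was 9.19% under E2. The ER overlap was highest with midpoints within 1 kb under E2 (20.9%) and without PR peaks shared between the treatments under E2+P4 (16 of 123 peaks). Clustering at 5 kb and 50 kb ran from 18.9% to 31.2% for E2 PR, from 28.6% to 43.8% for E2+P4 PR, from 6.79% to 44.4% for E2 ER and from 5.41% to 39.4% for E2+P4 ER. For ER, chance at 5 kb and 50 kb gave 3.09% and 25.9% under E2, and 2.79% and 24.0% under E2+P4. At or above the median scores, clustering was 40.8%, 49.5%, 9.11% and 8.53% in that order of lists. ER clustering was there 2.51 times chance under E2 and 2.59 times under E2+P4, against 2.40 and 2.23 times in the whole lists. The 10 fullest windows held 35.1%, 47.4%, 2.66% and 2.69% (chance 6.53%, 10.8%, 1.87% and 1.84%). In 5 Mb windows of the whole lists the 10 fullest held 24.9%, 36.2%, 7.93% and 7.03% (chance 8.61%, 12.0%, 5.02% and 4.68%). No paired analysis was possible because the lists give no values per replicate, and replicates could not be left out for the same reason. The alternatives fixed beforehand on promoters, motifs, gene lists, tRNA genes and differential binding were not run for want of an hg19 annotation or counts. Sequencing depth is unknown and limits what an absent peak can show.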

Other observations

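The tests of a hypothesis in this part were chosen after the counts per chromosome were seen, except the test of PR peaks beside ER peaks.

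RNA polymerase III transcribes tRNA genes, which lie in groups on a few human chromosomes. The GRCh38.p14 gene table places 443 tRNA genes on chromosomes 1 to 22 and X, 35.0% of them on chromosome 6, and 299 lie next to another tRNA gene. Chromosomes 6, 1, 17, 16, 5 and 14 held 133, 46, 26, 18, 15 and 12 such neighbours, and 61, 20, 26, 14, 14 and 12 clustered E2 PR peaks. Chromosome 7 was an exception, with 16 neighbours and 0 clustered PR peaks in either list, and chromosomes 4, 18 and 22 had 0 neighbours and 2 clustered E2 PR peaks each. For E2 PR the Pearson r was 0.956 (permutation p = 1e-05, the smallest possible, adjusted p = 0.00013) and the Spearman rho 0.820 (p = 1e-05, adjusted p = 6.5e-05). For E2+P4 PR they were 0.934 (permutation p = 2e-05, adjusted p = 0.00013) and 0.886 (p = 1e-05, adjusted p = 6.5e-05). Without chromosomes 6 and 1, r was 0.872 and 0.879, and rho 0.760 and 0.847. In all 13 relations were computed, with r and rho adjusted separately over the 13.

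The same count of tRNA neighbours had lower coefficients with clustered ER peaks, a difference from PR that was not tested, with r = 0.139 under E2 (permutation p = 0.541, adjusted p = 0.640; rho = 0.476, p = 0.0231, adjusted p = 0.0375) and r = 0.165 under E2+P4 (p = 0.503, adjusted p = 0.640; rho = 0.425, p = 0.0433, adjusted p = 0.0625). Clustered ER peaks rose with the number of protein-coding genes, with r = 0.706 under E2 (permutation p = 0.00033, adjusted p = 0.00107; rho = 0.604, p = 0.00287, adjusted p = 0.00933) and r = 0.741 under E2+P4 (p = 4e-05, adjusted p = 0.000173; rho = 0.646, p = 0.00122, adjusted p = 0.00529). Without chromosomes 1 and 21 these r were 0.507 and 0.640. Peaks and genes were counted per chromosome without dividing by its length or by all its peaks. Larger chromosomes can hold more of both, so these relations do not separate a tie to genes from chromosome size. Clustered PR peaks rose with protein-coding genes in rank, with rho = 0.519 under E2 (permutation p = 0.0122, adjusted p = 0.0264; r = 0.364, p = 0.0843, adjusted p = 0.124) and rho = 0.569 under E2+P4 (p = 0.00575, adjusted p = 0.0150; r = 0.366, p = 0.0859, adjusted p = 0.124). Without chromosomes 1 and 21 their rho were 0.416 and 0.482, and their r 0.297 and 0.319. For PR the rho with tRNA neighbours exceeded that with protein-coding genes by 0.301 under E2 (bootstrap interval 0.0525 to 0.622) and by 0.317 under E2+P4 (0.0935 to 0.635). It exceeded that with histone genes by 0.527 (0.0976 to 1.05) and 0.613 (0.179 to 1.17). These counts are unlike, since only tRNA genes were restricted to those beside a gene of their kind (299 of 443). The restriction resembles the definition of clustered peaks, and no rho with all tRNA genes was computed. A minimum difference of rho, first set as the criterion against those genes, lay inside all 4 intervals and decided nothing. Shares of peaks on chromosomes, already seen by then, were used in its place and describe the lists rather than test them independently. The r between clustered PR peaks and histone genes, 0.877 under E2 (permutation p = 0.0032, adjusted p = 0.00776) and 0.840 under E2+P4 (p = 0.00358, adjusted p = 0.00776), rested on chromosomes 6 and 1, being -0.0953 and -0.110 without them. The rho were 0.292 (p = 0.178, adjusted p = 0.193) and 0.272 (p = 0.206, adjusted p = 0.206). A hypothesis is that many clustered PR peaks, with and without added progesterone, lie at tRNA genes. The rho over all 23 chromosomes, 0.820 in the E2 list, goes with it, but chromosomes are coarse units and no peak was placed on a gene.

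E2-specific ER peaks may favour gene-rich chromosomes. Over 23 chromosomes, the log2 ratio of E2-specific to E2+P4-specific ER peaks rose with protein-coding genes per Mb (Spearman rho 0.493, permutation p = 0.0187, adjusted p = 0.0347; Pearson r 0.508, p = 0.0101, adjusted p = 0.0188). Without chromosomes 19 and 17 the r was 0.425 and the rho 0.378. Whether this reflects binding or a library difference such as GC content was not tested.

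PR beside ER without overlap was tested on dispersed E2 PR peaks. Of 574 such peaks, 109 overlapped an ER peak and 146, which include these, had an ER midpoint within 1 kb. The ratio of 1.34 lies between the values set in advance for and against it. Those values made no allowance for chance, so the ratio decides nothing. Over all E2 PR peaks, 15.2% overlapped an E2 ER peak and 20.9% had an ER midpoint within 1 kb. Random placement gave 0.167% overlapping and 0.634% within 1 kb. Both shares lay above chance, but random placement ignores open chromatin, so the excess alone does not show PR beside ER.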
